A study of Mus musculus with 8 samples.

How the data were processed

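Gene expression in thalamic tissue of 8 mice was measured on Affymetrix whole-transcript arrays. Per the labels' protocols, total RNA was extracted from the thalamic tissue of 2 mice per group and 300 ng was labelled for each array. Per the submitters' processing notes the authors used Affymetrix Expression Console and RMA, which corrects background, normalizes between arrays and summarizes the probes of a probe set. The deposited values are log2 levels, as their range (0.82 to 14.2) and medians (6.18 to 6.29) show. Tool versions, array library files and filters are not given in the sources used here. Replicates were not pooled in the table. RMA draws the arrays towards a common distribution, so a change in total RNA per cell is not seen, and small differences of dim probe sets are compressed.

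Genes were named through the platform annotation supplied with the table. Of 35557 probe sets, 21789 had 1 gene symbol, 1621 had several and 12147 were unnamed here. Probe sets with several symbols were tested but not named, and 21698 of the 1-symbol probe sets had an identifier that the reference gene table also holds. The 40% of probe sets with the lowest mean over the 8 arrays (mean log2 under 5.63) were left out, as were unnamed ones, which left 15791 (14895 with 1 symbol, 896 with several, 13524 genes). Of these, 128 held the same values as another probe set. The depth of an array is its signal over background, and no detection calls were used.

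The analysis used R 4.3.3 and limma 3.58.1. A mean per group was fitted to all 8 arrays with lmFit and moderated with eBayes (4 residual degrees of freedom, 2.53 prior degrees of freedom, median residual SD 0.207), so that the 4 groups share an estimate of the spread. Two-sided p-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was called past the threshold. An exact permutation test of 2 against 2 arrays cannot give a two-sided p under 0.333 and was not used. The count at an unadjusted p under 0.05 and at least 1.2-fold is descriptive. The comparisons were MPTP against control, acupoint against MPTP, non-acupoint against MPTP and acupoint against non-acupoint, with the mean of the 3 injected groups against control, the mean of both needled groups against MPTP and an F test over the groups besides.

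Gene lists covered cell types, neighbouring brain regions, stress and signalling, 30 in all with 499 symbols, of which 447 matched a probe set. The 29 lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated for each list and with fry. The adjusted p of camera and fry are over the 29 lists of a comparison. List medians use 1 probe set per gene, that with the highest mean. Camera with the preset correlation takes genes of a list as nearly independent, and genes of a tissue compartment are not.

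Genes were named in the text by a rule. It takes, for each of the 4 main comparisons, up to 10 higher and 10 lower genes of largest change among those past the threshold, with places filled by the smallest unadjusted p among genes whose 2 groups do not overlap. It adds up to 4 members of smallest p for each list past the threshold, and 10 genes in every case (Th, Slc6a3, Ddc, Maob, Gfap, Aif1, Fos, Ttr, Hbb-b1, Gdnf). Hbb-b1 had no named probe set. Genes without a proper name were passed over. Other genes, among them those past the threshold in 6 arrays, members of the dopaminergic list and Igf2 in MPTP against control, were chosen after their values were seen. Groups of 2 arrays do not overlap in 33.3% of probe sets by chance, counting both directions, and they did not in 38.5%, 27.1%, 12.4% and 31.8% of probe sets in the 4 comparisons in the order given above.

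The tests, gene lists, rule for naming genes and first alternatives were chosen before the data were examined. These alternatives were another quantile normalization, cyclic loess, no brightness filter, a filter at the dimmest 60%, an intensity trend and a robust fit in eBayes, array weights, fits on only the groups compared, the mouse number as a block, 1 probe set per gene, and leaving out each mouse in turn. Another 3 were added after the data were seen, namely the 6 arrays without the 2 that stood apart, a term for these 2 arrays, and unnamed probe sets included. The procedure was tested on simulated data for MPTP against control over 15791 probe sets. Each probe set had its real residual SD, taken as equal on all 8 arrays, with independent errors. The procedure recovered 38.8% of 67 planted 2-fold changes, 85.1% of 67 planted 4-fold changes and 87.9% of 66 planted 8-fold changes, with 8 false calls. In the real data 2 arrays deviated together, 1 of them in the MPTP group, so these rates do not describe that case. Camera recovered a planted list of 18 genes shifted by 1 log2 unit with 0 others called. The simulated genes were drawn independently and the lists filled at random. This check therefore cannot show how often camera calls lists of genes that vary together. Correlations of changes were set beside 100 simulated sets of unchanged groups, also drawn for the fits with fewer arrays. They were also set beside correlations in which 0.5 times the difference between mouse 1 and mouse 2 stood for the error of a group mean, averaged over both signs in the control and acupoint groups. This last reference was added after the correlations were seen.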

Results

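Gene expression was measured in thalamic tissue from 8 adult male C57BL/6 mice, an inbred laboratory strain, on Affymetrix whole-transcript arrays. The mice formed 4 groups of 2. Control mice received saline. Mice of the other 3 groups received MPTP, a neurotoxin that is taken up by dopaminergic neurons and is used to model parkinsonism, at 20 mg/kg every 24 hr for 4 weeks. The MPTP group received no needling, the acupoint group was needled at GB34 and LR3, acupuncture points of the lower leg and foot, in 14 sessions 48 hr apart, and the non-acupoint group was needled at the hips on the same schedule. Of the probe sets on the array, 15791, for 13524 genes, carried a gene name and passed the brightness filter. Median log2 levels per array lay between 6.18 and 6.29. The titles number the mice within each group. The p-values rest on the spread between the 2 mice of a group, pooled over all 4 groups. Leaving out a mouse of a group not compared therefore also changes them. The 2 mice correlated at r = 0.908 in the MPTP and 0.936 in the non-acupoint group, against 0.995 in controls and 0.993 in acupoint mice. The spread was thus not equal among groups. The number of arrays limits the precision of every value.

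The arrays of MPTP mouse 1 and non-acupoint mouse 1 stood apart from the other 6. Across probe sets their levels correlated with each other at r = 0.982 and with the other 6 arrays at 0.905 to 0.936, while the other 6 correlated with each other at 0.981 to 0.995. The first principal component, which held 71.8% of the variance, separated these 2 arrays from the rest. Genes of the cytosolic ribosome and of mitochondrial complex I were lower on them, by a median log2 difference from the other 6 arrays of -0.58 over 21 genes and -0.52 over 34 genes. Values for the 6 other arrays are therefore given beside those for all 8, a choice made after the data were seen. They leave the MPTP and non-acupoint groups with 1 array each, whose spread is assumed to be that of the other groups. Leaving out MPTP mouse 2 or non-acupoint mouse 2, as done below, makes an array that stood apart the whole of its group. The shift of that array then counts as a group difference. Higher counts without these mice therefore cannot be read as an effect of MPTP or needling.

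The first comparison asked what MPTP did to the thalamic transcriptome. Genes of the choroid plexus, the epithelium that secretes cerebrospinal fluid, were higher in MPTP mice than in controls. All 18 of the 18 measured genes of this list were higher, with a median log2 change of 1.45, and 16 passed when adjusted over the list alone. Kcnj13, which encodes an inward rectifier potassium channel of that epithelium, stood at a log2 level of 7.53 ± 0.04 in controls and 10.60 ± 0.66 in MPTP mice (SD, n = 2), an 8.39-fold difference. The folate receptor Folr1 was 3.36-fold higher and the BMP antagonist Sostdc1 4.53-fold higher. Transthyretin, Ttr, the carrier of thyroid hormone in cerebrospinal fluid, stood at 12.16 ± 0.16 and 13.28 ± 0.52.

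Markers of thalamic projection neurons were also higher in MPTP mice, with 16 of 18 genes higher, a median of 0.56 and 11 genes past the threshold when adjusted over the list alone. Among them were the kinase gene Prkcd (log2 change 0.85 ± 0.17, SE), the transcription factor gene Tcf7l2 (0.83), Vav3 (0.92 ± 0.17), and Ntng1, a netrin-related adhesion molecule (0.92). All 12 measured dopaminergic neuron genes were lower, with a median of -0.66 and 0 of them past the threshold over the list alone. Tyrosine hydroxylase, Th, the rate-limiting enzyme of dopamine synthesis, was 9.22 ± 0.17 in controls and 7.45 ± 1.84 in MPTP mice (SD, n = 2), with MPTP mouse 1 at 6.15 and mouse 2 at 8.75. The dopamine transporter Slc6a3 split in the same way, at 7.79 ± 2.26 in MPTP mice and 9.89 ± 0.10 in controls, and its change of -2.10 ± 0.95 (SE) did not pass (adjusted p = 0.714, limma with Benjamini-Hochberg adjustment).

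Hypothalamic genes were lower in all 16 measured members, with a median of -0.50 and 4 past the threshold over the list alone. These 4 were Hdc, which makes histamine (-1.29 ± 0.23, SE), the signalling adapter gene Irs4 (-1.11) and the hormone genes Oxt (-1.43) and Avp. Meningeal fibroblast genes were lower in 10 of 11 members (median -0.42, 5 lower over the list alone). They included the transporter genes Slc6a13 (-1.13 ± 0.19) and Slc22a6 (-0.74) and the matrix gene Fmod (-0.71), while the meningeal gene Igf2 was 0.56, in the other direction. Neuropeptide and opioid genes (median -0.17) and neurotrophic factor genes (-0.30) were lower. Those of smallest p were Adcyap1 (-0.91) and Nts (-0.88) in the first list and Gfra2 (-0.48) and Mdk (-0.35) in the second, and none passed over its list alone. Circadian clock genes were higher (14 of 15, median 0.32), as were glutamate receptor genes (18 of 19, median 0.19), of which Grm4 (0.80) and Grin2b (0.73) passed over the list alone. Heat shock and unfolded protein genes were lower (17 of 20, median -0.35), with the largest changes in Sdf2l1 (-1.32) and Hspa1a (-1.15). Cytosolic ribosome genes (median -0.42) and complex I genes (-0.26) were lower too. Without the 2 arrays that stood apart these 2 medians were -0.05 and 0.09, that for complex I in the other direction (camera adjusted p = 0.00285, adjusted p = 0.459 with an estimated correlation), and the glutamate receptor median was -0.01. The calls of ribosome and glutamate receptors were lost (camera adjusted p = 0.111 and 0.594). Without these 2 arrays the medians were also nearer to 0 for the dopaminergic (-0.31), hypothalamic (-0.21), meningeal (-0.28), neurotrophic (-0.17), circadian (0.11) and heat shock (-0.13) lists, and further from 0 for neuropeptides (-0.27).

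By limma over all 8 arrays no probe set passed an adjusted p of 0.05 in this comparison (smallest adjusted p = 0.0941, for Cldn1, a tight junction gene, log2 change 1.66 ± 0.13, SE), and 836 had an unadjusted p under 0.05, where chance gives 790. That count was 247 without control mouse 1, 280 without control mouse 2, 5573 without MPTP mouse 2 and 504 without acupoint mouse 1 or acupoint mouse 2. The 12 lists named above passed camera, with adjusted p from 4.90e-27 for choroid plexus and 6.98e-10 for thalamic neurons to 0.0202 for neuropeptides, and none passed with an estimated correlation (adjusted p from 0.10 to 0.607 with an estimated correlation). By fry, 4 passed. The complex I call was lost without control mouse 2 (adjusted p = 0.0528) or MPTP mouse 1 (0.0850), and the ribosome call without MPTP mouse 1 (0.628). With the 6 arrays, 57 probe sets for 45 named genes passed. They held 32 genes that were higher, with Ptpn3 (1.09, adjusted p = 0.0383), the peptide receptor gene Vipr2 (1.05), Prkcd (1.06) and the adenylyl cyclase gene Adcy1 (0.97) beside choroid plexus genes such as Aqp1 (1.70) and Ttr (1.49, adjusted p = 0.0383). The lower genes included Slc6a12 (-0.90), a betaine and GABA transporter, Slc6a13 (-1.21), Nrgn (-1.01), a calmodulin-binding protein of forebrain neurons, and Gabra5 (-0.83). Over all 8 arrays these changes were -0.97, -1.13, -0.19 and -0.46. The values for Nrgn and Gabra5 rest on MPTP mouse 2 (7.33 and 7.85). In MPTP mouse 1 Nrgn stood at 8.97, above both controls (8.28 and 8.39), and Gabra5 at 8.61, near them (8.73 and 8.64).

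**Figure D1:**
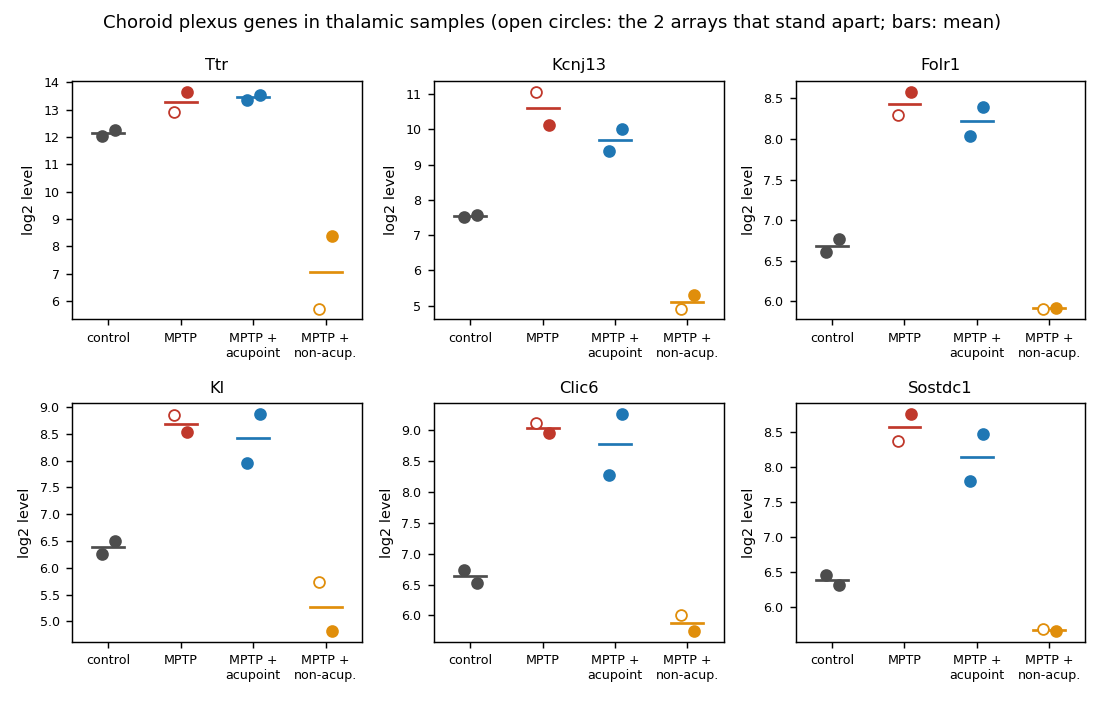
Log2 levels of 6 choroid plexus genes on each of the 8 arrays, by group (circles, 1 per mouse; bars, group mean; open circles, the 2 arrays that stand apart). Ttr stood at 5.72 and 8.39 in the non-acupoint mice and between 12.05 and 13.65 in the other 6 mice.

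The comparison of non-acupoint needling with MPTP alone gave the only probe sets past the threshold over all 8 arrays, 7 genes that were all lower, 3 of them on the choroid plexus list and 1 on the meningeal list. All 18 measured choroid plexus genes were lower after hip needling (median log2 change -2.11), and all 18 passed when adjusted over the list alone. Kcnj13 (probe set 10356403) fell from 10.60 ± 0.66 to 5.11 ± 0.27 (SD, n = 2; log2 change -5.49 ± 0.35, SE; limma adjusted p = 0.0197). Folr1 (probe set 10566034) changed by -2.52 (adjusted p = 0.0197, limma) and Sostdc1 (probe set 10395389) by -2.90 (adjusted p = 0.0394). Outside that list, Cldn1 (probe set 10438769, -1.83), the carbonic anhydrase gene Car12 (-2.93) and Lbp, which binds bacterial lipopolysaccharide (-2.83), also fell. So did the growth factor gene Igf2 of the meningeal list (-1.69, limma adjusted p = 0.0420). From highest to lowest, the group means of each of these genes ran MPTP, acupoint, control, non-acupoint, as those of the choroid plexus list did. Being off that list therefore does not set their fall apart from it. The non-acupoint levels of Kcnj13 and Cldn1 (5.57 ± 0.05) lie under the mean of 5.63 that the brightness filter asks for, where differences are compressed, so the size of their fall is uncertain.

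The change of Ttr was larger but less even between the mice, -6.23 ± 0.78 (SE), with non-acupoint mice at 5.72 and 8.39 (adjusted p = 0.138, limma). Clic6 (-3.16 ± 0.31, adjusted p = 0.0609), Calml4 (-1.86) and the collagen gene Col8a1 (-1.43) did not pass over all genes. Meningeal fibroblast genes were lower in all 11 members (median -0.14, 2 past the threshold over the list alone, Igf2 and Slc6a20a at -0.99). Ependymal genes of motile cilia were lower in 7 of 7 (median -0.44), with the largest change in Dynlrb2 (-1.08), and habenula genes in 10 of 11 (median -0.32), with the largest changes in Gpr151 (-0.98) and the nicotinic receptor subunit genes Chrnb4 (-0.89) and Chrnb3 (-0.70). Glucocorticoid response genes were lower in 10 of 13 (median -0.25), with Sgk1 at -0.73 and Fkbp5 at -0.58. Calml4, Dynlrb2, Gpr151 and Chrnb4 also had non-acupoint means under the 5.63 of the brightness filter, so the size of these changes is uncertain.

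Striatal (median -0.42), cortical (-0.16), cytokine (-0.20) and dopaminergic (-0.32) lists were also lower after hip needling. The hypothalamic (0.23), ribosomal (0.08) and thalamic neuron (0.11) lists were higher, with Trh, the thyrotropin-releasing hormone gene, at 0.71 and Oxt at 0.79. In the striatal and cortical lists MPTP mouse 1 stood alone, at 0.95 and 0.38 from the mean of the 8 arrays, with the other 7 at most at 0.21 and -0.01. The phosphatase genes Dusp4 (0.56) and Dusp1 (0.59), which damp MAP kinase signalling, had the smallest p of the genes that were higher, without passing the test (adjusted p = 1.00 for Dusp4, limma). These 12 lists passed camera, with adjusted p from 2.51e-96 for choroid plexus to 0.0392 for thalamic neurons. Choroid plexus also passed with an estimated correlation (adjusted p = 0.0248 with an estimated correlation) and by fry (0.00646), and the other 11 did not (adjusted p from 0.0812 to 0.866 with an estimated correlation). The choroid plexus call, too, was lost with an estimated correlation when only the 6 arrays were used (adjusted p = 0.606 with an estimated correlation). By limma over all 8 arrays, 246 probe sets had an unadjusted p under 0.05. None of the 7 past the threshold stayed past it without control mouse 1, control mouse 2, MPTP mouse 1 or either non-acupoint mouse. Without MPTP mouse 2 only Kcnj13 of the 7 did, and without either acupoint mouse only some of the 7 did. The unadjusted count was 151 without control mouse 1 or control mouse 2, 1093 without MPTP mouse 1, 1374 without MPTP mouse 2, 373 without non-acupoint mouse 1 and 542 without non-acupoint mouse 2. The dopaminergic call turned to higher without MPTP mouse 2 (median 0.28, adjusted p = 0.0215) and was lost without non-acupoint mouse 1 (0.123) or mouse 2 (0.370), the ribosomal call turned to lower without MPTP mouse 1 (-0.27, adjusted p = 0.000619) and was lost without non-acupoint mouse 2 (0.0727). The hypothalamic call was lost without MPTP mouse 1 (0.394) or non-acupoint mouse 1 (0.207), the thalamic call without any of the 4 MPTP and non-acupoint mice (0.0536 to 0.835), and the number of lists was 7 without non-acupoint mouse 1. With the 6 arrays each of these groups held 1 array, so changes of single genes are given as sizes only. Kcnj13 changed by -4.83, Ttr by -5.26 and Slc6a3 by -1.56. Over all 8 arrays the change of Slc6a3 was -0.56, it did not pass, and the groups overlapped. MPTP mouse 1, left out of the 6, lay below both non-acupoint mice in Slc6a3, so no fall after hip needling can be read from it. With the 6 arrays the hypothalamic (-0.02), striatal (0.35), cortical (0.05) and habenula (0.09) medians had the other sign. These 4 lists and the ribosomal (0.03) and thalamic (0.02) lists then lost their calls (camera adjusted p from 0.238 to 0.938), and the ependymal, meningeal and dopaminergic medians were -0.29, -0.26 and -0.48.

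Needling at GB34 and LR3 was compared with MPTP alone to ask what acupoint treatment changed. No single gene passed. Thalamic projection neuron genes were higher in 16 of 18 members (median 0.26), with Rgs16, a regulator of G protein signalling, at 0.77 ± 0.19 (SE) and Vav3 at 0.48. Habenula genes were higher in 9 of 11 (median 0.25), with the habenular receptor gene Gpr151 at 6.25 ± 0.43 in MPTP and 7.53 ± 0.54 in acupoint mice (SD, n = 2). The groups overlapped in the habenula list mean. It stood at 0.52 and -0.35 in MPTP mice 1 and 2, and at 0.17 and 0.69 in acupoint mice 1 and 2. GABA receptor genes were higher in 8 of 11 (median 0.11), of which Gabra4 (0.50) and Gabra2 (0.37) had the smallest p. Dopaminergic genes were lower in 9 of 12 (median -0.51), and Th stood at 6.09 ± 0.18 in acupoint mice. Choroid plexus genes were lower in 14 of 18 (median -0.24), far from the non-acupoint levels, with Kcnj13 at 9.71 ± 0.44.

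Ribosomal genes (median 0.27), complex I genes (0.22) and heat shock genes (0.24) were higher and striatal genes lower (-0.34) after acupoint needling. Without the 2 arrays that stood apart, these medians were -0.07, -0.08, 0.04 and 0.17. By camera with the preset correlation, the calls of ribosome and complex I then turned to lower. Those of heat shock and striatum were lost. The habenula, GABA receptor and dopaminergic medians were then 0.75, 0.18 and -0.87, against MPTP mouse 2 alone. In the habenula list the MPTP mouse left out was the higher one, so its larger median is no firmer. The lower striatal median rests on MPTP mouse 1, in which the striatal gene Rgs9 stood at 10.36 against 7.12 to 8.71 on the other 7 arrays. The genes with the smallest p were Zic1 (0.75 ± 0.14, SE) and Zic2 (0.69), zinc finger transcription factors, Dusp4 (0.72), Socs6 (0.83), Spry4 (0.54), Sestd1 (0.61), Adamts15 (0.56) and the ciliary gene Tmem212 (0.80) among those higher. Among those lower were Cldn1 (-0.71), Ceacam2 (-0.76), the neurotensin receptor gene Ntsr1 (-0.67), the oligodendrocyte gene Opalin (-0.75), Leprot (-0.74), Nxph4 (-0.81), St6galnac2 (-0.46), Serpind1 (-0.46) and the mitochondrial carrier gene Slc25a13 (-0.60). Each had an adjusted p of 0.889 by limma, the smallest of this comparison, where 216 probe sets had an unadjusted p under 0.05 against 790 by chance. That count was 78 without control mouse 1 or control mouse 2, 378 without MPTP mouse 1, 4133 without MPTP mouse 2, 80 without acupoint mouse 1, 62 without acupoint mouse 2 and 392 without non-acupoint mouse 1 or non-acupoint mouse 2. The 9 lists passed camera, with adjusted p from 9.61e-07 for thalamic neurons to 0.0486 for striatum, and none passed with an estimated correlation (adjusted p from 0.309 to 0.620 with an estimated correlation) or by fry. With MPTP mouse 2 left out, 5 lists passed, and the dopaminergic (0.918) and choroid plexus (0.521) calls were lost, the latter also without acupoint mouse 1 (0.943). Without MPTP mouse 1 the ribosomal call turned to lower (-0.07, adjusted p = 0.0255) and that of complex I was lost (0.0777). With the 6 arrays 3 genes passed, all dopaminergic and lower: Slc6a3 (-3.30, adjusted p = 0.000627), Th (-2.66, adjusted p = 0.0146) and the nicotinic receptor subunit gene Chrna6 (-1.75, adjusted p = 0.0281), against MPTP mouse 2 alone, where Th stood at 8.75. The acupoint means of Ceacam2 and Chrna6 lie under the 5.63 of the brightness filter, so the size of their changes is uncertain.

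The acupoint and non-acupoint groups were compared directly. They differed in the site of needling and in part in its depth, 1 mm at LR3 and 3 mm at GB34 against 3 mm at the hips. Choroid plexus genes were higher after acupoint than after hip needling in all 18 members (median 1.92), and all 18 passed when adjusted over the list alone. Ttr stood at 13.45 ± 0.12 in acupoint and 7.05 ± 1.89 in non-acupoint mice (SD, n = 2), a change of 6.39 ± 0.78 (SE), and Kl, which encodes klotho, at 8.41 ± 0.64 and 5.27 ± 0.64. Habenula genes were higher in all 11 members (median 0.53), and Gpr151 (2.25 ± 0.35), Chrnb4 (1.14) and Nwd2 passed over the list alone. Ependymal genes were higher in all 7 (median 0.67), with Tmem212 (1.15) past the threshold over the list alone, and so were meningeal genes (11 of 11, median 0.33), with Igf2 (1.22), Slc6a20a (0.80) and the proteoglycan gene Dcn (0.61). The non-acupoint means of Kl, Gpr151, Chrnb4, Tmem212 and Kcnj13 lie under the 5.63 of the brightness filter, which leaves the size of their changes uncertain.

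Thalamic neuron genes were higher after acupoint than after hip needling in 15 of 18 (median 0.19), with the T-type calcium channel gene Cacna1g at 0.43. So were the glucocorticoid (0.22), heat shock (0.26) and complex I (0.25) lists. Hypothalamic genes were lower in 11 of 16 (median -0.33), with Trh (-1.01 ± 0.20, SE) past the threshold over the list alone. Calcr (-0.99), a calcitonin receptor, Gabrq (-1.02), a GABA receptor subunit, and the imprinted genes Asb4 (-0.82) and Dlk1 (-1.01) were among the lower genes of smallest p (adjusted p = 0.893 for each, limma), and the acupoint means of Calcr and Asb4 lie under 5.63 as well. Neuropeptide genes (median -0.21, with Trh again of smallest p) and oligodendrocyte genes (-0.18, with Opalin at -0.50) were lower as well. No probe set passed over all genes by limma. Kcnj13 (4.60 ± 0.35) and Folr1 (2.30 ± 0.18) had the smallest adjusted p of 0.0522, Lbp (2.50) followed at 0.0681, and 299 probe sets had an unadjusted p under 0.05, a count that was 167 without control mouse 1 or control mouse 2, 629 without MPTP mouse 1 or MPTP mouse 2, 142 without acupoint mouse 1, 109 without acupoint mouse 2, 183 without non-acupoint mouse 1 and 1998 without non-acupoint mouse 2. The number past the threshold was 1 without MPTP mouse 1, MPTP mouse 2 or non-acupoint mouse 2. The 11 lists passed camera, with adjusted p from 1.30e-52 for choroid plexus to 0.0248 for glucocorticoid response, and none passed with an estimated correlation (adjusted p from 0.0687 to 0.678 with an estimated correlation). The thalamic call was lost without non-acupoint mouse 2 (0.339) and that of complex I without non-acupoint mouse 1 (0.740). By fry, choroid plexus (0.0101) and meninges (0.0211) passed. With the 6 arrays 21 probe sets passed, 16 of them higher, and the glucocorticoid, heat shock and complex I medians were -0.01, 0.02 and -0.04, with their calls lost (camera adjusted p = 0.538, 0.392 and 0.706). The hypothalamic and oligodendrocyte medians were -0.21 and -0.30.

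Setting the mean of the 3 injected groups against control put more arrays into the MPTP arm. Thalamic neuron genes were higher in 17 of 18 members (median 0.68), and 13 passed when adjusted over the list alone. This list passed camera (adjusted p = 6.37e-17) and kept its call with an estimated correlation (adjusted p = 0.0464 with an estimated correlation) and by fry (0.00335). Meningeal genes were lower in all 11 members (median -0.48, 8 past the threshold over the list alone, camera adjusted p = 2.95e-11, adjusted p = 0.0464 with an estimated correlation). Both lost their call with an estimated correlation in the 6 arrays (adjusted p = 0.434 and 0.434 with an estimated correlation). Dopaminergic genes were lower in all 12 members (median -0.98, 7 past the threshold over the list alone), with Slc6a3 at -2.85 ± 0.78, Slc18a2, the vesicular monoamine transporter, at -2.44 ± 0.47, and Th at -2.35 ± 0.62 (SE), among the 7. Their camera call (adjusted p = 1.73e-09) was lost with an estimated correlation (adjusted p = 0.209 with an estimated correlation). Hypothalamic genes were lower in all 16 (median -0.41, camera adjusted p = 1.81e-09, adjusted p = 0.209 with an estimated correlation).

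By limma over all 8 arrays, no single probe set passed in the injected groups against control (smallest adjusted p = 0.0922, 1102 at an unadjusted p under 0.05 and at least 1.2-fold), while 855 passed with the 6 arrays. The genes with the smallest p there were Ptpn3, a tyrosine phosphatase (1.28, adjusted p = 0.00459), Vav3 (1.03), Prkch (1.11), Osbpl3 (0.96), the synaptic scaffold gene Shank3 (0.97), Ntng1 (0.87) and Vipr2 (1.05) among those higher. Among those lower they were Slc6a3 (-2.12, adjusted p = 0.00123), Chrna6 (-1.50), Th (-1.81), Mab21l2 (-1.21), Dlk1 (-0.98), Fmod (-0.86), Slc6a12 (-0.95) and the peptide gene Cartpt (-1.31). The unadjusted count was 329 without control mouse 1, 356 without control mouse 2, 3684 without MPTP mouse 2, 651 without acupoint mouse 1 and 656 without acupoint mouse 2, and 9 probe sets passed without MPTP mouse 2. For the mean of both needled groups against MPTP, no probe set passed over all 8 arrays (smallest adjusted p = 0.191, 213 at an unadjusted p under 0.05 and at least 1.2-fold, 116 without control mouse 1 or control mouse 2, 707 without MPTP mouse 1, 2982 without MPTP mouse 2, 118 without acupoint mouse 1, 120 without acupoint mouse 2 and 558 without non-acupoint mouse 1) and 13 did with the 6. Of the choroid plexus genes, 18 of 18 were lower in that comparison (median -1.23, camera adjusted p = 9.41e-53, adjusted p = 0.0789 with an estimated correlation). Limma's F test over the 4 groups called 0 probe sets over all 8 arrays (559 at an unadjusted p under 0.05) and 422 with the 6.

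**Figure D2:**
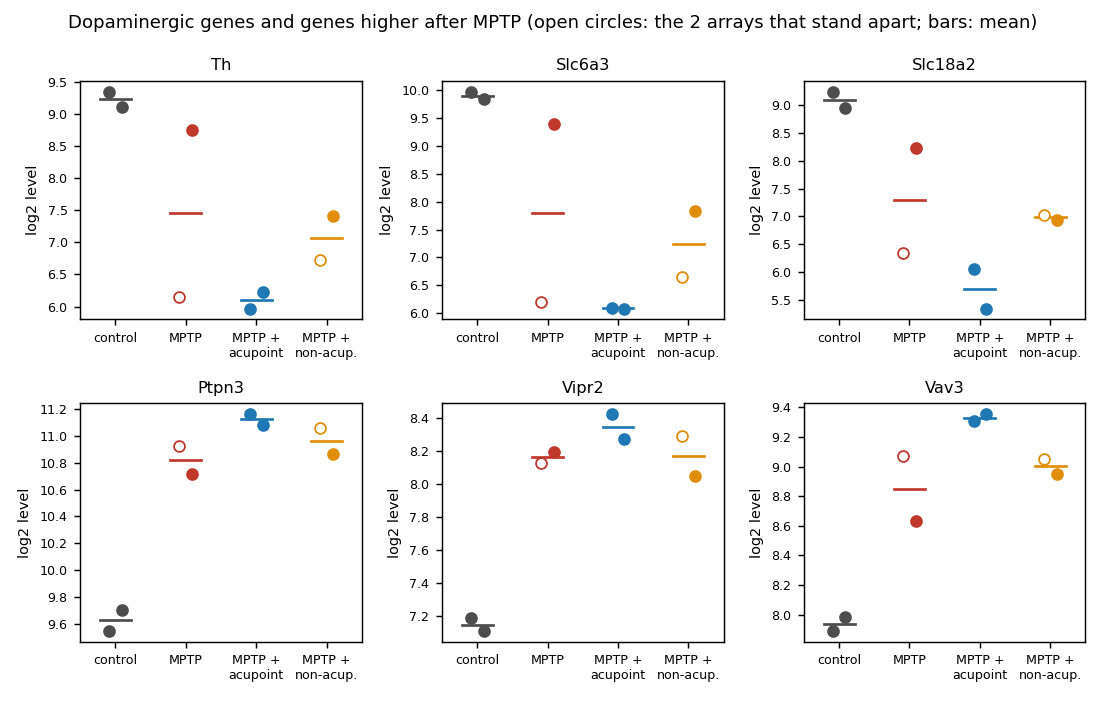
Log2 levels on each array of 3 dopaminergic genes (Th, Slc6a3, Slc18a2) and 3 genes higher in the injected groups (Ptpn3, Vipr2, Vav3), by group (circles, 1 per mouse; bars, group mean; open circles, the 2 arrays that stand apart). MPTP mouse 2 lay near the controls in Th (8.75 against 9.10 in control mouse 2), and the acupoint mice at 5.97 and 6.22.

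**Figure D3:**
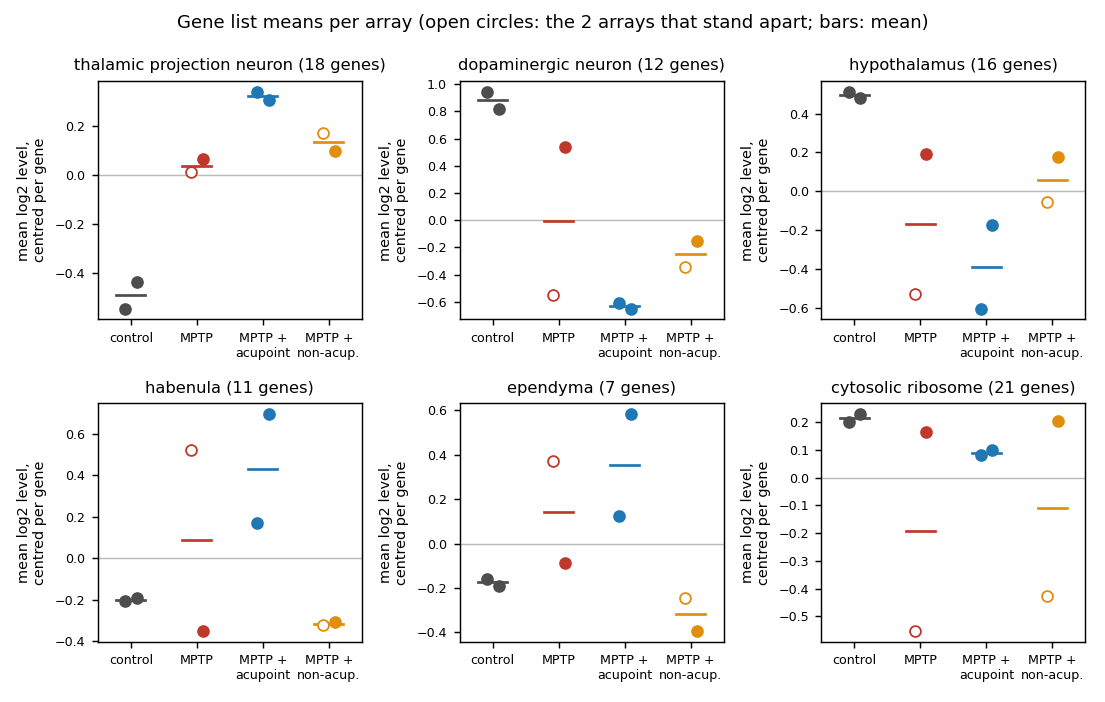
Mean level of 6 gene lists on each array, each gene centred on its mean over the 8 arrays (log2 units; circles, 1 per mouse; bars, group mean; open circles, the 2 arrays that stand apart). The thalamic list was lowest in the controls (-0.54 and -0.44) and highest in the acupoint mice (0.34 and 0.30), and the ribosomal list was lowest on the 2 arrays that stand apart (-0.55 and -0.43).

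Whether needling moved genes against the MPTP change was asked by correlating log2 changes across the 15791 probe sets, which are not independent replicates. Changes in acupoint against MPTP correlated with those in MPTP against control at r = -0.69 (Spearman -0.68). Both comparisons hold the MPTP arrays, and 100 simulated sets of unchanged groups gave a mean r of -0.50 (-0.53 to -0.47). The covariance was -0.0694 against -0.0478 simulated. The r with the 6 arrays was -0.28, against -0.67 simulated. For hip needling the same correlation was -0.34 (Spearman -0.24), against a simulated -0.50 (covariance -0.0244 against -0.0477), and -0.52 with the 6 arrays, against -0.58 simulated. The changes of both needled groups against MPTP correlated at 0.28 (Spearman 0.30), against a simulated 0.50 (covariance 0.0163 against 0.0476), and 0.65 with the 6 arrays, against 0.58 simulated. With 2 MPTP arrays the shared group was not split between the comparisons. The first correlation was -0.28 without MPTP mouse 1 and -0.91 without MPTP mouse 2, the second -0.89 without MPTP mouse 2, -0.76 without non-acupoint mouse 1 and 0.36 without non-acupoint mouse 2, and the third 0.87 without MPTP mouse 2, 0.81 without non-acupoint mouse 1 and -0.48 without non-acupoint mouse 2. Simulated values for these settings were -0.67, -0.67 and 0.67 without an MPTP mouse, and -0.41 to -0.40, -0.41 to -0.40 and 0.41 without a mouse of another group compared.

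Acupoint against non-acupoint and MPTP against control share no array. Their changes correlated at -0.43 (Spearman -0.53) over all 8 arrays, where independent unchanged groups gave -0.04 to 0.04, and at 0.39 with the 6, in the other direction, where they gave -0.04 to 0.03. Each of these 2 comparisons holds an array that stood apart, and r was also positive without MPTP mouse 1 alone (0.33) or non-acupoint mouse 1 alone (0.31). The simulated groups are independent of each other, whereas MPTP mouse 1 and non-acupoint mouse 1 deviated from their groups together. A value without group effects that keeps this was built from the difference between the mice of each group, with the MPTP and non-acupoint groups sharing a sign. It was -0.94, -0.52 and 0.51 for the 3 correlations above and -0.76 for this one, each further from 0 than the value observed over all 8 arrays. Over the 8 arrays, none of the 4 correlations can therefore be read as an effect of needling. The simulations drew each probe set independently, so their ranges are narrower than genes that vary together would give. No value that keeps shared deviations was built for the 6 arrays. The correlations with the 6 arrays therefore cannot be read as an effect of needling either.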

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

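All tests of explanations in this part were chosen after the results were seen, except that of the markers of ventral neighbours, whose list and prediction were written before its values were computed. The 6-array values were also added after the data were seen.

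The effects of acupoint and of non-acupoint needling against the same MPTP mice differed for 11 gene lists by camera on the difference itself, and for none of them with an estimated correlation (adjusted p from 0.0687 to 0.678 with an estimated correlation). The median difference of acupoint minus non-acupoint was 1.92 log2 units for choroid plexus, 0.67 for ependyma, 0.53 for habenula, 0.33 for meningeal fibroblasts, 0.26 for heat shock and unfolded protein genes, 0.25 for complex I, 0.22 for glucocorticoid response and 0.19 for thalamic projection neurons. It was -0.33 for hypothalamus, -0.21 for neuropeptides and -0.18 for oligodendrocytes. By camera with the preset correlation, 8 of the 11 kept their direction and call with the 6 arrays, and heat shock, complex I and glucocorticoid response did not.

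MPTP mouse 1 and non-acupoint mouse 1 stood apart from the other 6 arrays, which belong to different groups. Their shift against the other 6 was higher for genes of longer genomic span (Spearman correlation 0.402 across 13491 genes). The median shift was -0.21 for the shortest 25% of genes and 0.28 for the longest 25%. Span includes introns and is only a rough stand-in for transcript length. For 37 snoRNA and snRNA genes the median was -0.64, and 75.7% of them were lower. Lower recovery of short transcripts on these 2 arrays would give this pattern. Span alone cannot tell it from other differences in the RNA of these samples. An exchange of the 2 arrays between their groups would not by itself set both apart from all 6 others. If choroid plexus levels mark the group, that list also argues against an exchange of the 2 arrays. In it MPTP mouse 1 lay nearer to MPTP mouse 2 than to non-acupoint mouse 2 by 2.38 log2 units. Whether they share tissue of another region cannot be told, since 0 of 10 regional lists had both arrays outside the range of the other 6 by over 0.3, but that range was up to 2.57 wide, and MPTP mouse 1 alone was high in the striatal (0.95) and cortical (0.38) lists, where non-acupoint mouse 1 was at -0.11 and -0.03. What set the 2 samples apart at the bench was not tested, and no biological explanation was tested because the pair crosses the groups.

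Choroid plexus genes were high in MPTP and acupoint mice, intermediate in controls and low in non-acupoint mice. The 2 arrays that stand apart are argued against as its source, since non-acupoint mouse 2 minus MPTP mouse 2 had a median of -2.39 over the 18 genes. These genes varied together, with 100% of them lower in both non-acupoint arrays than in both MPTP arrays and a median pairwise r of 0.943 over the 8 arrays, which restates the observation and supports neither explanation. Ttr ranged from 5.72 to 13.65. Different amounts of choroid plexus in the dissected samples and an action of MPTP or needling on choroid plexus cells cannot be told apart. Levels that follow the group go with both. A wide gap between mice of the same group was predicted for dissection only. It was not seen, since the mice of a group differed by at most 0.510 in the list mean. Its absence does not decide, because dissection may also have followed the group.

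Dopaminergic genes were lower and thalamic neuron genes higher in the 3 injected groups than in controls. The 2 arrays that stand apart are argued against as the whole cause, since the dopaminergic median was -0.759 without them. Markers of ventral neighbours of the thalamus that are not dopaminergic were lower too, in all 9 of the 9 measured genes of 20 (median -0.456; camera p = 3.60e-08, and p = 0.0915 with an estimated correlation), among them Gata3 (-1.15) and Cartpt (-1.74), which is consistent with less ventral tissue in the injected samples. The hypothalamic list mean was also lower in the MPTP (-0.168), acupoint (-0.388) and non-acupoint (0.061) groups than in controls (0.495). Of the 12 dopaminergic genes 83.3% lay lower in both MPTP mice than in both controls, which restates the observation. The prediction for loss of dopaminergic neurons after MPTP also asked that the ventral markers not be lower, and they were. Loss therefore gains no support here. Lower ventral markers do not forbid it, so both explanations stay open for these genes. Within groups the ventral markers did not follow Th throughout, since mouse 1 had less Th than mouse 2 in the MPTP (6.15 and 8.75) and non-acupoint (6.72 and 7.40) groups but was lower in 9 of the 9 markers in the first (median -0.51) and 5 in the second (median -0.04), and mouse 1 of both groups stands apart.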

How the results depend on the processing

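The settings with the 6 arrays, a term for the 2 arrays that stood apart and unnamed probe sets were chosen after the data were seen. Over all 8 arrays, probe sets past the threshold numbered 0, 0, 7, 0, 0, 0 in the order MPTP against control, acupoint against MPTP, non-acupoint against MPTP, acupoint against non-acupoint, injected against control and both needled groups against MPTP, which all lists of 6 values below follow, and those at an unadjusted p under 0.05 and at least 1.2-fold numbered 836, 216, 246, 299, 1102, 213. With the 6 arrays the first counts were 57, 3, 23, 21, 855 and 13 and the second 2077, 1947, 2310, 1103, 2031 and 2102, with 422 by the F test against 0. With a term for the 2 arrays they were 12, 0, 42, 13, 333 and 5, and 1670, 813, 914, 882, 1780 and 678, with 206 by the F test. Both settings remove the variance of these 2 arrays from the spread. With the term, 15 lists passed in acupoint against MPTP, against 9. Of the ribosome and complex I medians, those that follow turned in both settings. The complex I median was 0.0890 and 0.0635 in MPTP against control (main -0.26), -0.0806 and -0.0499 in acupoint against MPTP (main 0.22) and -0.0431 and -0.0595 in acupoint against non-acupoint (main 0.25). The ribosomal median was -0.0673 and -0.0545 in acupoint against MPTP (main 0.27) and -0.12 and -0.14 in acupoint against non-acupoint (main 0.17). The hypothalamic median in non-acupoint against MPTP was -0.0183 with the 6 arrays (main 0.23). The correlation of acupoint against MPTP with MPTP against control was -0.28 with the 6 arrays (simulated -0.67 in unchanged groups) and -0.13 with the term, and that of acupoint against non-acupoint with MPTP against control turned to 0.39 and 0.38.

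Without a brightness filter, which adds probe sets, the unadjusted counts were 1299, 399, 486, 502, 1900 and 431, 2 probe sets passed in acupoint against non-acupoint, 1 in injected against control and 5 by the F test. With the dimmest 60% left out the unadjusted counts were 536, 135, 102, 155, 721 and 109, and 6 lists passed in non-acupoint against MPTP against 12. With an intensity trend 2 probe sets passed in acupoint against non-acupoint and 3 by the F test, and with 1 probe set per gene 3 and 3. Array weights gave 0 in non-acupoint against MPTP, 2 in acupoint against non-acupoint, 230 in injected against control and 2 by the F test, and unadjusted counts of 539, 81, 62, 3117 and 38 (acupoint against non-acupoint apart). Fits on only the groups compared gave 0 in non-acupoint against MPTP and unadjusted counts of 484, 102 and 84 in the first 3 comparisons and 116 in the last, while for injected against control this setting is the fit to all 8 arrays. With unnamed probe sets included, 4 passed in non-acupoint against MPTP. With an estimated correlation 0, 0, 1 and 0 lists passed in the 4 main comparisons, and by fry 4, 0, 1 and 2, against 12, 9, 12, 11. Beyond what is said of construction here, the cause was not tested.

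The mouse numbers do not pair the samples, which come from different mice and whose deviations from the group means correlated between -0.28 and 0.82. With the mouse number as a block, 5 probe sets passed in non-acupoint against MPTP and 0 in the other 5 comparisons, the unadjusted count in acupoint against MPTP was 339, and 12, 7, 12 and 13 lists passed in the 4 main comparisons. Car12 and Igf2 in non-acupoint against MPTP then had adjusted p of 0.0675 and 0.0679. Mouse 1 of the MPTP and non-acupoint groups are the 2 arrays that stood apart, and the 0.82 is the correlation between these 2 groups.

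Leaving out each mouse in turn leaves a group with 1 array, whose spread is assumed to be that of the others. Without MPTP mouse 2 or non-acupoint mouse 2 that array is 1 that stood apart, and its shift counts as a group difference. Probe sets past the threshold ranged over 0 to 5 in non-acupoint against MPTP, 0 to 1 in acupoint against non-acupoint and 0 to 9 in injected against control. Unadjusted counts ranged over 247 to 5573, 62 to 4133, 151 to 1374, 109 to 1998, 329 to 3684 and 116 to 2982, the highest without MPTP mouse 2 except in acupoint against non-acupoint, where it was without non-acupoint mouse 2. Lists past the threshold ranged over 5 to 13 in acupoint against MPTP and 7 to 13 in non-acupoint against MPTP. The 4 correlations, in the order of the report, ranged over -0.91 to -0.28, -0.89 to 0.36, -0.48 to 0.87 and -0.59 to 0.33, with the signs of the middle 2 turned without non-acupoint mouse 2 and that of the last without MPTP mouse 1 or non-acupoint mouse 1. Of the 7 lists followed through these settings (choroid plexus, thalamic, dopaminergic, hypothalamic, meningeal, ribosomal and complex I), the medians that changed sign were complex I (-0.55 to 0.0890 in MPTP against control, -0.0806 to 0.55 in acupoint against MPTP, -0.30 to 0.36 in non-acupoint against MPTP and -0.0431 to 0.51 in acupoint against non-acupoint), ribosome (-0.0673 to 0.59 in acupoint against MPTP, -0.27 to 0.40 in non-acupoint against MPTP and -0.12 to 0.42 in acupoint against non-acupoint), hypothalamus (-0.20 to 0.46) and dopaminergic neurons (-0.78 to 0.28) in non-acupoint against MPTP, and hypothalamus in acupoint against MPTP (-0.34 to 0.12). Other lists were not followed. Their medians that changed sign with the 6 arrays include striatum in acupoint against MPTP (0.17), glutamate receptors in MPTP against control (-0.01), glucocorticoid response in acupoint against non-acupoint (-0.01), and striatum, cortex and habenula in non-acupoint against MPTP (0.35, 0.05 and 0.09).

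Of 258 named gene results, 7 were past the threshold, and 34 changed sign in at least 1 of 20 alternatives. All 7 fell below the threshold in fits on only the groups compared, with array weights, and without either control, without MPTP mouse 1 and without either non-acupoint mouse. Quantile normalization once more, cyclic loess and a robust fit left every count of probe sets past the threshold within 1.5 times its value. The robust fit was not run for the gene lists, since camera has no such setting. The arrays' signal over background was not measured, so the filter on dim probe sets stands in for depth.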

Other observations

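No glial or immune list passed in MPTP against control over all 8 arrays. The microglia list had a median log2 change of -0.13 in MPTP against control (camera adjusted p = 0.250), astrocytes -0.24 (0.0612), oligodendrocytes -0.15 (0.343), interferon response -0.13 (0.324), cytokines -0.11 (0.866) and antioxidant genes -0.10 (0.250). With the 6 arrays the microglia (-0.19, adjusted p = 0.00254) and astrocyte (-0.32, adjusted p = 0.00200) lists passed as lower, and neither did with an estimated correlation (adjusted p = 0.442 and 0.505 with an estimated correlation). Gfap, the intermediate filament of astrocytes, was -0.69 ± 0.32 (SE, n = 2 per group, limma adjusted p = 0.714), and the microglial gene Aif1 -0.15 ± 0.21. Maob, which converts MPTP to its toxic form, was 0.80 ± 0.52 over all 8 arrays and -0.01 with the 6. Gdnf, a trophic factor for dopaminergic neurons, was -0.12 ± 0.20.

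Fos, a marker of neuronal activity, was -0.50 ± 0.23 in MPTP against control, 0.34 ± 0.23 in acupoint and 0.35 ± 0.23 in non-acupoint against MPTP (log2, SE), and none of these passed (limma adjusted p = 0.714, 0.889 and 1.00). The immediate early list had a median of 0.06 in acupoint and 0.06 in non-acupoint against MPTP (camera adjusted p = 0.169 and 0.517). Genes linked to Parkinson disease (0.00), GABA neurons (-0.13), dopamine receptors and breakdown (-0.12) and endothelium (0.26) had camera adjusted p of 0.774, 0.343, 0.369 and 0.139 in MPTP against control. Ddc, which makes dopamine from its precursor, was -0.92 ± 0.41 in MPTP against control and -1.29 ± 0.34 in the 3 injected groups against control.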
